A study of Mus musculus with 16 samples.

How the data were processed

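Per the labels, 16 whole-brain RNA samples from separate C57BL/6 neonates at postnatal day 1 were each hybridized to 1 one-colour array, with 4 animals per group: offspring of fresh sperm, of freeze-dried sperm, of freeze-dried sperm irradiated with 5 Gy of X-rays and of freeze-dried sperm heated at 95 °C for 1 h. The labels give each neonate a number but do not say what its parts mean, so whether animals share a litter is not known, and littermates would make the p-values too small. In the fresh group the first part of that number changes together with the slide, so the slide and whatever this number stands for cannot be told apart there.

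The authors scanned the arrays and extracted them with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The deposited scanner files hold fluorescence intensity (background-subtracted and detrended processed signal, and raw median spot and background signals) with quality flags of 0 or 1 per spot, and the values are not scaled between arrays. The deposited value table holds log2 signals of 31313 probes that follow nearly the same distribution in every array; how it was made is not stated. Its column medians were 9.337, 9.343, 9.336 and 9.339 for fresh 1 to 4, 9.335, 9.342, 9.342 and 9.344 for freeze-dried 1 to 4, 9.34, 9.344, 9.341 and 9.348 for irradiated 1 to 4, and 9.341, 9.34, 9.344 and 9.341 for heated 1 to 4. Compared with quantile-normalized scanner values, 88.6% of the squared differences lay between the slides, and the shift of each probe followed its slide difference with slope -0.8 (r = -0.9999 across probes, which are not independent replicates). Probes with a slide effect numbered 2672 in the scanner values and 0 in the table, and probes that differed between heated and freeze-dried animals 1563 and 0. The table was therefore used as an alternative only, and the scanner intensities were the source of all reported values.

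Each array has 62976 spots, of which 3671 are controls. Spots of the same probe were averaged (56605 probes, 45622 distinct genes or features), 50 values marked as outlier spots were left out, and 0 spots were saturated. The processed signal was put on the log2 scale and scaled by the 75th percentile of each array. A probe was kept when it was well above background on all 4 arrays of at least 1 group (34261 probes), and the brightest probe stood for each gene, which left 26479 genes and features: 15993 with a RefSeq gene symbol and 10486 without. Features without a symbol were counted and not named. Between 59.9% and 66.1% of spots per array were well above background, the 75th percentile of the signal ranged from 1043 to 1412 and the median coefficient of variation of repeated probes from 2.55% to 7.62%. The extraction software placed all its quality measures in range for 12 arrays and marked 1 or more to evaluate for 4.

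All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8, for reading) with 4 group means, 12 residual degrees of freedom and moderated two-sided tests. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. A fold against a group in which no array was well above background is given as a lower bound. Gene lists were written from general knowledge: 47 lists of stress and damage responses, brain cell types and regions, tissues next to the brain, imprinted genes and sex-linked genes, each with at least 3 measured genes. They were tested with camera at its preset correlation of 0.01 against all other genes, with camera at an estimated correlation and with fry. fry asks whether the genes of a list move one way on balance, without comparing them with other genes. Camera, the estimated correlation and fry were applied to the irradiated against fresh, heated against fresh and irradiated against heated comparisons only after the gene counts had been seen. Spread among animals was compared by two-sided exact permutation over the 70 assignments of 8 animals. The shares of the variance between arrays explained by groups and by slides were compared with 1e+05 and 20000 permutations.

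The design, the gene lists, the comparisons and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule for named genes was as follows, and a few genes that meet it are not reported here. For freeze-dried against fresh, irradiated against freeze-dried and heated against freeze-dried, it names the 12 largest increases and 12 largest decreases that passed and did not overlap between groups, or up to 10 genes with the smallest p where fewer than 10 passed. For the other 3 comparisons it names the 3 largest changes each way. From each shifted list it allows up to 4 members with the smallest p. Cdkn1a, Mdm2, Hspa1a, Hspa1b, Igf2, H19, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty are always named; Xist was not well above background on all arrays of any group and so was not tested. The marker genes of single arrays (Gh, Prl, Pomc, Krt14, Acta1, Hoxb5, Hoxc4 and Pcp2) were named after their values were seen.

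The workflow was tested on simulated data built from the residuals of the 16 arrays. With 200 changed genes in each of 10 runs, a 2-fold change was found in 82.2%, 82.4% and 85.6% of cases for freeze-dried against fresh, irradiated against freeze-dried and heated against freeze-dried, and a 1.5-fold change in 61.4%, 58.4% and 63.8%, with a median of 1, 2.5 and 1 false calls. The simulation mixed the residuals of all arrays at random, so slide, sex and brain region no longer followed particular arrays. Its counts of false calls therefore do not cover such differences between the real groups. The number of arrays limits precision: the median SE of a difference was 0.101 on the log2 scale. A list moved by 0.3 was found in 10 of 10 runs with the preset correlation in each of these comparisons and in 7, 7 and 5 with the estimated correlation. With no list moved the preset correlation still called a median of 5.5, 7.5 and 7 lists. The 200 changed genes were present in these runs too, and as they were drawn from all genes some could lie in a list.

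Alternatives were normexp background correction (offset 50, applied to the median spot and background signals in place of the planned mean signal, which was not used here), quantile normalization, median centring, no filter, a filter on all 16 arrays, the mean of a gene's probes, each probe on its own, slide or scan batch as a block, replicate number as a block, array weights, the Y-linked signal as a covariate, the deposited value table, fits on 8 arrays, fits within a slide and leaving out each array. Added after seeing the data were the Hox signal as a covariate, slide block with the Y-linked covariate, permutation of groups within slides, and leaving out the arrays with pituitary, muscle or skin signal or the arrays low in Hox genes. Slide and scan batch are the same split of the arrays. Replicate numbers did not pair the arrays: profiles with the same number correlated at a median r of 0.03 across genes (24 pairs, 10 of them above 0.1), so the block on replicate number was an alternative only.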

Results

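Brains of mice at postnatal day 1 were compared between offspring of fresh sperm, freeze-dried sperm, freeze-dried sperm given 5 Gy of X-rays and freeze-dried sperm held at 95 °C for 1 h, with 4 animals and 4 arrays per group. Levels are log2 signals relative to the 75th percentile of each array, given as mean ± SD of 4 animals, and differences between groups are given with their standard error (SE).

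Genes that mark sex, brain region and neighbouring tissue separated single animals within the groups. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were high together in 10 animals, namely 2 of the fresh, 4 of the freeze-dried, 3 of the irradiated and 1 of the heated group. Xist, the RNA that silences an X chromosome in females, was between -0.88 and -0.48 in the other 6 animals and between -7.99 and -5.99 in these 10. Hoxb5, which marks hindbrain and spinal cord, lay at -7.49 in fresh 2, -6.05 in freeze-dried 2, -7.17 in heated 2 and -7.75 in heated 4, against -1.61 to 1.12 in the other 12 animals. The Purkinje cell gene Pcp2 was at -2.55 in heated 2 and -3.73 in heated 4, and at 0.81 to 1.24 in the other 14. The pituitary hormone gene Gh reached 2.87 in fresh 3, 2.38 in freeze-dried 1 and 2.71 in heated 1, where the other arrays were between -7.73 and -5.6. The skin keratin Krt14 was at 2.49 in freeze-dried 2 alone, and the muscle actin Acta1 at 1.77 in fresh 1 alone. The arrays lay on 2 slides. Slide 1 held fresh 1 and 2, all 4 freeze-dried and irradiated 1 and 2, and slide 2 held fresh 3 and 4, irradiated 3 and 4 and all 4 heated animals, so no slide held both freeze-dried and heated samples. The fresh animals on slide 2 differed from those on slide 1 in 555 genes, the irradiated animals in 2.

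**Figure D1:**
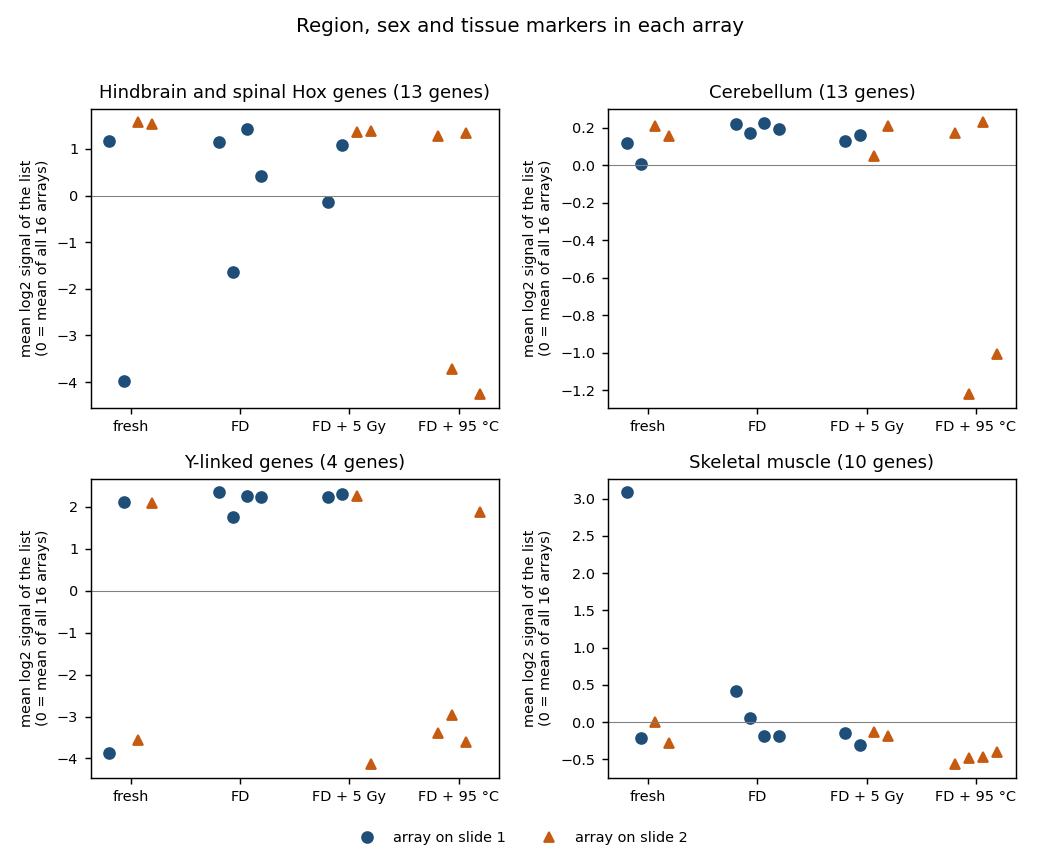
Mean log2 signal of 4 marker lists in each of the 16 arrays, centred on the mean of all arrays, by sperm treatment; circles are arrays on slide 1 and triangles arrays on slide 2. Hox genes are low in fresh 2 (-3.97), freeze-dried 2 (-1.64), heated 2 (-3.71) and heated 4 (-4.25), and muscle genes are high in fresh 1 (3.09).

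Between offspring of freeze-dried and of fresh sperm, the list with the smallest adjusted p was that of immediate early genes, the transcription factors and phosphatases that cells switch on quickly after a stimulus. These genes were shifted upward as a list, by 0.34 on the log2 scale over 18 genes, 17 of them higher (adjusted p = 8.54e-08; 0.513 with an estimated correlation). The low values were those of the fresh animals on slide 1 (-0.404 and -0.619, centred on all arrays), while fresh 3 and 4 on slide 2 (-0.14 and -0.04) lay near the freeze-dried animals (-0.049 to 0.112). Between the slides the fresh animals differed by 0.421, with 16 of 18 genes higher on slide 2. Nr4a1 was at 1.99 ± 0.08 against 1.53 ± 0.27 in the fresh group, Klf4 at 1.82 ± 0.22 against 1.34 ± 0.22 and Dusp1 at 2.12 ± 0.11 against 1.82 ± 0.12. Markers of the choroid plexus, the tissue that secretes cerebrospinal fluid, were higher in 14 of 15 genes (mean 0.23, adjusted p = 0.00324; 0.926 with an estimated correlation), among them its transcription factor Otx2 (0.25) and the potassium channel Kcnj13 (0.45). No single gene passed: 0 of 26479 genes and features changed by limma, 2628 had an unadjusted p under 0.05 where chance gives 1324, and the smallest adjusted p was 0.217. That value belonged to Fut4, a fucosyltransferase, which was lower by a log2 difference of -0.46 (SE 0.07, -3.08 ± 0.09 against -2.61 ± 0.15). The next smallest p-values were those of the inhibitory antibody receptor Fcgr2b (0.47), the actin nucleator Spire2 (-0.30), Nckap5l (-0.38), the melanocortin receptor partner Mrap (0.50), the replication origin protein Orc1 (-0.54) and the receptor Gpr6 (-0.49). Pnisr (0.41), the synaptic scaffold gene Ppfia2 (-0.39) and the immediate early gene Ier2 (0.35) followed. Their adjusted p ran from 0.282 to 0.333.

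Among the lists, 7 of 47 were shifted between the freeze-dried and the fresh group, 4 upward and 3 downward, and with an estimated correlation 0 of 47 were. In simulated data in which no list was moved, though 200 single genes were, the same test called a median of 5.5 lists and at most 13. In the immediate early list 0 of 18 genes passed over all genes tested and 8 rose adjusted over the list alone; the mean shift was 0.455 with slide as a block and 0.55 within slide 1. In the choroid plexus list 0 of 15 genes passed over all genes and 2 rose adjusted over the list alone. Meninges and fibroblasts (18 genes, mean 0.089, adjusted p = 0.00821, Postn 0.44 and Dcn 0.32) and microglia (16 genes, mean 0.11, adjusted p = 0.0224, Tyrobp 0.28 and Laptm5 0.32) were shifted upward. Cholesterol synthesis (19 genes, mean -0.070, adjusted p = 0.00476, Dhcr7 -0.21), synapse genes (28 genes, mean -0.051, adjusted p = 0.0192, Nlgn1 -0.21, while Gria2 was 0.22 higher) and skeletal muscle (10 genes, mean -0.625, adjusted p = 0.00821) were shifted downward. With an estimated correlation the adjusted p was 0.926 for each of these 5 lists. The muscle value came from fresh 1, which carried high Acta1, and it was 0.189 without that array (adjusted p = 0.358). Only the immediate early list passed whichever of the 16 arrays was left out. Without freeze-dried 1 the choroid plexus (0.16, adjusted p = 0.15), meninges (0.063, 0.15), microglia (0.094, 0.192) and synapse (-0.039, 0.15) lists no longer passed, and without fresh 2 neither did cholesterol synthesis (-0.036, 0.275) nor microglia (0.088, 0.275). The meninges list also failed without fresh 4 (0.089, 0.0779) and the synapse list without fresh 1 (-0.043, 0.185), fresh 4 (-0.036, 0.114) or freeze-dried 2 (-0.019, 0.181). With slide as a block the microglia and meninges lists did not pass (adjusted p = 0.159 and 0.126). The other 40 lists were not shifted (adjusted p from 0.0983 to 0.976), among them p53 targets (mean 0.040), DNA repair (0.0020), heat shock and chaperones (-0.026) and imprinted genes (0.020). The growth factor Igf2 and the imprinted RNA H19 did not differ (-0.04 and 0.14, adjusted p = 0.868 and 0.596), nor did Cdkn1a (0.06, 0.808), Mdm2 (-0.03, 0.913), Hspa1a (-0.20, 0.479) or Hspa1b (-0.20, 0.66). The Y-linked genes, high in 4 of 4 freeze-dried and 2 of 4 fresh animals, differed by 2.06 (Uty) to 3.56 (Kdm5d) without passing.

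After X-irradiation of freeze-dried sperm interferon response genes were higher as a list in the brains of the pups, though 0 of the 19 genes passed singly and the groups overlapped. All 19 genes of this antiviral list were higher than in the freeze-dried group (mean 0.51, adjusted p = 1.35e-10; 0.415 with an estimated correlation). Among them were Isg15 at 1.41 ± 0.56 against 0.66 ± 0.40, Oas1a at -0.93 ± 0.37 against -1.57 ± 0.24 and Gbp3 at -0.74 ± 0.20 against -1.27 ± 0.19. The list mean differed among the irradiated animals, from 0.825 in irradiated 2 and 0.375 in irradiated 1 to 0.103 in irradiated 3 and -0.128 in irradiated 4, where irradiated 1 and 2 were on slide 1. The freeze-dried animals lay at -0.486, -0.071, 0.078 and -0.373, so that freeze-dried 2 and 3 were above irradiated 4. The p53 target Cdkn1a, which stops the cell cycle after DNA damage, did not differ (1.34 ± 0.10 against 1.34 ± 0.14, adjusted p = 0.99). Neither did Mdm2 (-0.08, adjusted p = 0.789) or the p53 target list (26 genes, mean -0.036, adjusted p = 0.15). No single gene passed, with 0 of 26479 genes and features by limma and 1912 at an unadjusted p under 0.05 where chance gives 1324. The kinase activator gene Mob3c came closest (-0.65, SE 0.09, adjusted p = 0.0852, -4.52 ± 0.16 against -3.88 ± 0.13). The serotonin receptor Htr1d (0.54) and the thioredoxin inhibitor Txnip (0.53) followed at adjusted p = 0.223, then C2cd4b (0.63, 0.381) and the splicing kinase Clk1 (-0.58, 0.434). Arrdc3 (0.39), Csrnp1 (0.38), Cwc22 (-0.32), Bhlha15 (-0.97) and Iqca (0.48) followed at adjusted p = 0.452. The heat shock gene Hspa1a (0.34, adjusted p = 0.583), Hspa1b (0.22, 0.72), Igf2 (-0.08, 0.746) and H19 (-0.15, 0.706) did not pass either, nor did the Y-linked genes (from -1.87 for Kdm5d to -0.84 for Uty).

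In all, 13 of 47 lists were shifted between the irradiated and the freeze-dried group, 6 upward and 7 downward, and 0 with an estimated correlation. Simulated data with 200 changed genes but no moved list gave a median of 7.5 and at most 14. In the interferon list 0 of 19 genes passed over all genes tested and 7 rose adjusted over the list alone; the mean was 0.64 with slide as a block and 0.81 within slide 1. Cilia genes of the ependyma, the lining of the ventricles, were higher in 12 of 12 genes (mean 0.16, adjusted p = 0.00295; 0.415 with an estimated correlation; Dynlrb2 0.25), with 0.23 within slide 1. Ribosomal protein genes were lower in 39 of 43 (mean -0.082, adjusted p = 8.06e-08; 0.46 with an estimated correlation; Rps24 -0.14, Rps6 -0.14). Cell cycle genes were lower in 30 of 34 (mean -0.10, adjusted p = 7.18e-06; 0.587 with an estimated correlation; Aurka -0.21, Cenpa -0.18). Neural progenitors (18 genes, mean -0.14, adjusted p = 0.00898; Neurog2 -0.72) and blood leukocytes (8 genes, mean -0.33, adjusted p = 0.00898; Elane -0.19) were shifted downward. So were DNA repair (39 genes, mean -0.046, adjusted p = 0.0175; Lig4 -0.22), DNA methylation and chromatin regulators (25 genes, mean -0.053, adjusted p = 0.0175; Smarca4 -0.12) and imprinted genes (49 genes, mean -0.033, adjusted p = 0.0375; Cdkn1c -0.12). The adjusted p of these 5 lists with an estimated correlation ran from 0.415 to 0.488. Glucocorticoid response (14 genes, mean 0.125, adjusted p = 0.0105, 2 rose adjusted over the list alone; Klf9 0.40) and immediate early genes (18 of 18 higher, mean 0.17, adjusted p = 0.0184; Egr1 0.57) were shifted upward. Synapse (28 genes, mean 0.065, adjusted p = 0.0296; Camk2b 0.17) and oligodendrocyte lineage (15 genes, mean 0.098, adjusted p = 0.0296; Sox10 0.28) were too. With an estimated correlation the adjusted p of these 4 lists ran from 0.488 to 0.643. With slide as a block the DNA repair, imprinted, glucocorticoid and immediate early lists did not pass (adjusted p = 0.182, 0.182, 0.115 and 0.389). The block called 10 lists in all, 9 of them among these 13 and in the same direction, so it also called a list not shifted without it. Only the interferon, ribosomal, cell cycle and progenitor lists passed whichever of the 16 arrays was left out. Without irradiated 1, a total of 7 lists passed, and cilia (0.128, adjusted p = 0.0561), leukocytes (-0.283, 0.0561), glucocorticoid (0.122, 0.0552), immediate early (0.166, 0.0932), imprinted (-0.035, 0.0703), chromatin (-0.052, 0.0612) and oligodendrocyte (0.086, 0.117) lists did not. Leukocytes and glucocorticoid response also failed without freeze-dried 4 (-0.082, 0.321 and 0.127, 0.0535), and DNA repair without freeze-dried 1 (-0.040, 0.051), freeze-dried 2 (-0.039, 0.06) or irradiated 2 (-0.040, 0.0739). The chromatin, imprinted, immediate early, synapse and oligodendrocyte lists failed without at least 1 further array, at adjusted p of up to 0.269. The other 34 lists were not shifted (adjusted p from 0.0717 to 0.993), among them hypoxia response (mean 0.010), heat shock and chaperones (0.032), apoptosis (0.0030) and oxidative phosphorylation (0.0060).

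Heating of freeze-dried sperm to 95 °C was followed by higher expression of genes for motile cilia and lower expression of genes for cell division, although neither list passed with an estimated correlation (adjusted p = 0.107 and 0.177). The ciliary genes Ccdc153 (-0.75 ± 0.28 against -1.81 ± 0.16 in the freeze-dried group), Iqca (-1.93 ± 0.21 against -2.94 ± 0.15), Crocc2 (-2.01 ± 0.16 against -3.19 ± 0.20) and the dynein chain Dynlrb2 (1.60 ± 0.15 against 1.02 ± 0.15) rose. The proliferation marker Mki67 fell from 2.54 ± 0.04 to 2.12 ± 0.13, and Car9, a carbonic anhydrase induced by low oxygen, rose from -4.07 ± 0.34 to -3.08 ± 0.26. A total of 1021 of 26479 genes and features changed (661 rose and 360 fell; 783 with and 238 without a gene symbol), 32 of them at least 2-fold, with 6312 at an unadjusted p under 0.05. The 4 heated and 4 freeze-dried values did not overlap in 997 of the 1021, and in 20.3% of all genes tested, where chance gives 2.86%. These groups shared no slide. The count was 0 with slide as a block, with 2102 at an unadjusted p under 0.05 by limma. All 1021 genes then kept their sign, their median change was 0.27 in place of 0.40 and its median SE 0.106 in place of 0.088. On slide 2 alone, the 1021 genes differed between heated and fresh animals by a median of 0.216 in the same direction (96.3% with the same sign) and between heated and irradiated animals by 0.213 (99.1%), which is partly built in, since the heated animals also served to pick these genes. Fresh animals of slide 2 differed from those of slide 1 by 0.16 (86.2%), and irradiated animals by 0.08 (70.7%). The same genes also differed between irradiated and freeze-dried animals, by a median of 0.143 in the direction of heat (91.1%) and 0.102 within slide 1 (83.1%). Between freeze-dried and fresh animals the median was -0.091 (22.9% with the same sign). The freeze-dried animals also served to pick these genes, so these values are partly built in as well. The count was 142 with the Y-linked signal as a covariate and 12 without the 4 arrays low in Hox genes, a fit chosen after the data were seen. Without 1 array it was 539, 227 and 548 without freeze-dried 1, 2 and 3, then 528, 181, 489 and 286 without heated 1, 2, 3 and 4, and 1554 without fresh 1.

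Of the genes named for the heated against the freeze-dried group, the receptor kinase gene Musk rose most, by 2.76 (SE 0.46, adjusted p = 0.0107, well above background in 4 of 4 heated and 1 of 4 freeze-dried animals). The homeobox gene Dlx4 rose by 1.42 (SE 0.17, adjusted p = 0.00377), and Crocc2 by 1.18 (0.00377). Tmem212 rose by 1.06 (0.00824), Ccdc153 by 1.06 (SE 0.13, adjusted p = 0.00377) and Iqca by 1.01 (SE 0.10, adjusted p = 0.00086). Gzma (1.47), Ifi27l2a (1.08), the dynein Dnah10 (1.03), Gpr37l1 (1.03), the interferon-induced GTPase Tgtp2 (1.02) and the serotonin receptor Htr1f (1.00) made up the 12 largest increases, with adjusted p from 0.0146 to 0.031. Among the largest decreases, the transcription factors Nkx2-3 (-0.89, adjusted p = 0.0155) and Zic2 (-0.81, 0.0111) and the glycolipid anchor transamidase subunit Pigt (-0.83, 0.0119) fell. Wfikkn1 (-0.93), Lrg1 (-0.98), Mogat2 (-0.82), Ebf2 (-0.82), Raly (-0.77), Atf3 (-0.77), Fgf3 (-0.73) and Irx2 (-0.70) also fell (adjusted p from 0.0143 to 0.047). So did Otos, which was not well above background in any heated animal and was at least 1.01-fold lower. Of the 59 genes that are named for this comparison and passed, 15 passed whichever of the 16 arrays was left out, namely Musk, Dlx4, Crocc2, Tmem212, Ccdc153, Iqca, Nkx2-3, Pigt, Zic2, Car9, Ciart, Mki67, Camk2b, Gpr6 and Dynlrb2. The other 44 lost the call without at least 1 array, 41 of them without freeze-dried 2, 41 without heated 2 and 33 without heated 4, and 0 changed sign. Of the 59, 0 passed with slide as a block, and the smallest adjusted p were those of Iqca and Ccdc153 (0.0912 each, 0.97 and 1.26).

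Of the 47 lists, 19 were shifted between the heated and the freeze-dried group, 8 upward and 11 downward. By fry 11 passed, and 0 passed with an estimated correlation. Simulated data with 200 changed genes but no moved list gave a median of 7 and at most 13. All 12 cilia genes were higher (mean 0.43, adjusted p = 2.38e-07; 0.107 with an estimated correlation). Over all genes tested 6 rose, and 9 did adjusted over the list alone, Rsph1 by 0.45. The mean was 0.46 with slide as a block. In each heated animal the cilia list mean exceeded that of every other animal, and the group means were -0.211 ± 0.065 fresh, -0.126 ± 0.085 freeze-dried, 0.030 ± 0.090 irradiated and 0.306 ± 0.086 heated. Cell cycle genes were lower in 33 of 34 (mean -0.30, adjusted p = 5.96e-16; 0.177 with an estimated correlation). Over all genes 11 fell and 27 adjusted over the list alone, among them the spindle factor Tpx2 (-0.60), the replication helicase subunit Mcm5 (-0.67) and the centromere histone Cenpa (-0.41). Their mean was -0.22 with slide as a block. All 16 hypoxia response genes were higher (mean 0.29, adjusted p = 2.38e-07; 0.107 with an estimated correlation; 6 rose, 11 adjusted over the list alone). They included Car9 (0.98), the vasodilator peptide gene Adm (0.73), Ndrg1 (0.34) and the glycolytic enzyme gene Aldoa (0.22). Their mean was 0.26 with slide as a block. The interferon list was higher in 19 of 19 genes (mean 0.52, adjusted p = 1.14e-05; 0.429 with an estimated correlation; 2 rose, 10 adjusted over the list alone; Oas1a 0.97). Isg15 (0.75, adjusted p = 0.106) and Irf7 (0.64, 0.11) did not pass. Synapse genes (28 genes, mean 0.17, adjusted p = 1.14e-05; 0.18 with an estimated correlation; 4 rose, 11 adjusted over the list alone) included the kinase subunit gene Camk2b (0.41), the glutamate receptor Gria3 (0.29), Syt1 (0.29) and Nlgn1 (0.37).

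**Figure D2:**
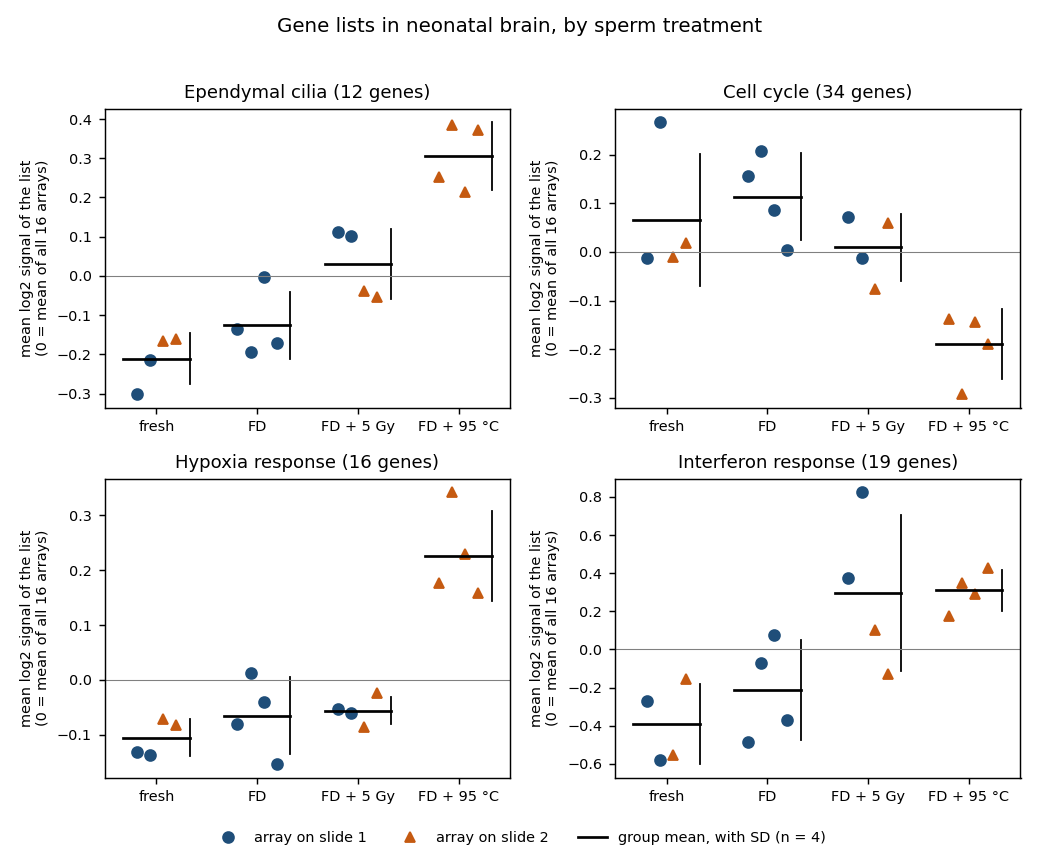
Mean log2 signal of 4 gene lists in each of the 16 arrays, centred on the mean of all arrays, by sperm treatment. Circles are arrays on slide 1, triangles arrays on slide 2, horizontal lines group means and vertical lines 1 SD to each side. Cilia and hypoxia genes lie highest in the 4 heated animals (group means 0.306 and 0.226) and cell cycle genes lowest (-0.19), and interferon genes are highest in irradiated 2 (0.825).

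Further lists that were shifted between the heated and the freeze-dried group include astrocytes, striatum, the circadian clock and progenitors. Astrocyte genes (14 genes, mean 0.24, adjusted p = 0.00782; 2 rose, Gfap by 0.78 and the glutamate transporter Slc1a2 by 0.43) and striatal neurons (14 genes, mean 0.16, adjusted p = 0.0124; Gpr6 rose by 0.60 and Rgs9 by 0.34, while Ebf1 fell by 0.63) were shifted upward. Also higher were the circadian clock (14 genes, mean 0.21, adjusted p = 0.00166; the repressor Ciart rose by 0.68) and the glucocorticoid response (14 genes, mean 0.16, adjusted p = 0.0124; Pdk4 rose by 0.41 and Klf9 by 0.48). Neural progenitors (18 genes, mean -0.15, adjusted p = 0.0124) were shifted downward, with the neurogenic factors Eomes (-0.62) and Insm1 (-0.42) and the cofactor Tead2 (-0.62) among the genes that fell. Imprinted genes (49 genes, mean -0.055, adjusted p = 0.00782) included 4 that fell, H19 (4.44 ± 0.04 against 4.81 ± 0.13, adjusted p = 0.027), the growth inhibitor Cdkn1c (-0.27), Nnat (-0.29) and Trappc9 (-0.31, but 0.10 with the mean of its probes). Igf2 did not differ (-0.03, adjusted p = 0.807). DNA repair (39 genes, mean -0.11, adjusted p = 0.000556) and meninges and fibroblasts (18 genes, mean -0.14, adjusted p = 0.00434; 1 fell, Postn by 0.49) were shifted downward. Blood leukocytes (8 genes, mean -0.68, adjusted p = 0.00122; 0 passed over all genes, 4 fell adjusted over the list alone; Lcn2 -0.77, adjusted p = 0.0563) and ribosomal proteins (43 genes, mean -0.029, adjusted p = 0.0449) were lower as well. Thalamic and midbrain neurons (14 genes, mean -0.16, adjusted p = 0.00221; 2 fell, Irx2 and Shox2 at -0.43) and cerebellum (13 genes, mean -0.66, adjusted p = 0.000556; 2 fell, Zic2 and En2 at -0.57) were lower, as was the Hox list (13 genes, mean -1.67, adjusted p = 0.0328). Astrocyte genes were at 0.303 and 0.309 in heated 1 and 3 but at 0.048 and 0.024 in heated 2 and 4, within the freeze-dried range (-0.22 to 0.075), and striatal genes at 0.026 and 0.056 in heated 1 and 3 and 0.176 and 0.147 in heated 2 and 4. The cerebellum list stood at -1.22 and -1.009 in heated 2 and 4, while heated 1 and 3 (0.171 and 0.229) lay with the freeze-dried animals (0.17 to 0.222). The leukocyte list was highest in freeze-dried 4 (1.099, others -0.052 to 0.276). The Hox list was low in heated 2 and 4 and in freeze-dried 2 and 0.312 higher once the arrays low in Hox genes were left out. The Y-linked list was lower (4 genes, mean -4.18, adjusted p = 0.0136), with 1 of 4 heated and 4 of 4 freeze-dried animals high in these genes. With an estimated correlation the adjusted p was 0.107 for DNA repair, circadian clock, thalamic neurons and imprinted genes, 0.132 for striatal neurons, 0.367 for leukocytes and 0.381 for progenitors. It was 0.429 for cerebellum, meninges, glucocorticoid response and Y-linked genes, 0.431 for astrocytes and 0.715 for the Hox and ribosomal lists. With slide as a block the meninges, glucocorticoid, progenitor, Y-linked and ribosomal lists did not pass (adjusted p = 0.118, 0.369, 0.0919, 0.118 and 0.17). The block called 23 lists in all, 14 of them among the 19 and in the same direction. Some lists that were not shifted without the block thus passed with it. The striatal list did not pass without heated 2, the Hox list without freeze-dried 1, 3 or 4 or heated 2 or 4, and the ribosomal list without any one of 7 arrays; the 16 others passed whichever array was left out. The 28 lists that were not shifted (adjusted p from 0.0525 to 0.988) include p53 targets (mean -0.066, adjusted p = 0.0525, 3 fell), heat shock and chaperones (-0.034, 0.237), immediate early genes (0.010, 0.667) and choroid plexus (0.027, 0.988). Hspa1a (0.08, adjusted p = 0.588), Hspa1b (-0.28, 0.252), Cdkn1a (-0.09, 0.504), Mdm2 (-0.08, 0.542), Eif2s3y (-5.67, SE 2.15, 0.13), Ddx3y (-3.98, 0.128), Kdm5d (-4.14, 0.237) and Uty (-2.93, 0.197) did not pass.

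Of the genes with a symbol named for irradiated against fresh animals, the early response gene Egr1 had the largest change among those that passed and rose by 1.38 (SE 0.24, adjusted p = 0.0162; 1.80 within slide 1 and 0.96 within slide 2). The chemokine Ccl7 (1.28, adjusted p = 0.0488) and the protease inhibitor gene Wfikkn1 (1.13, 0.0159) rose, and the proneural factor Neurog2 (-0.96, 0.0403), Bhlha15 (-0.93, 0.04) and Kbtbd8 (-0.77, SE 0.10, 0.00439; -0.77 and -0.78 within the slides) fell. Only Kbtbd8 of these 6 passed whichever of the 16 arrays was left out. Cdkn1a (0.06), Mdm2 (-0.11), Hspa1a (0.14), Hspa1b (0.02), Igf2 (-0.12), H19 (-0.01), Eif2s3y (1.72), Ddx3y (1.30), Kdm5d (1.70) and Uty (1.22) did not pass (adjusted p from 0.362 to 0.964). In total 364 genes and features changed, 229 higher and 135 lower, 52 at least 2-fold, with 4477 at an unadjusted p under 0.05; the split was 195 and 180 under quantile normalization and 110 and 98 after normexp correction. Of these, 170 had no gene symbol, and among the 52 larger changes 48 had none. The 4 and 4 values did not overlap in 360 of the 364, and in 9.09% of all genes where chance gives 2.86%. In a fit with slide as a block 651 genes changed, including all 364; within slide 1 the count was 414 and within slide 2 it was 1, with 2095 at an unadjusted p under 0.05 by limma. It was 152 with the Y-linked signal as a covariate, 71 without the filter, 69 on the 8 arrays of the 2 groups and 0 without the 4 arrays low in Hox genes. Without 1 array the count was 139, 111 and 185 without fresh 1, 2 and 3, then 88, 61, 54 and 186 without irradiated 1, 2, 3 and 4, and 217, 211 and 217 without heated 1, 2 and 3. The lists shifted in this comparison were 15 of 47, 8 upward and 7 downward. By fry 4 of the 47 passed, and 0 with an estimated correlation. Interferon genes were higher in 19 of 19 (mean 0.68, adjusted p = 2.76e-10; 0.476 with an estimated correlation; 2 rose, 16 adjusted over the list alone), by 1.03 within slide 1 and 0.34 within slide 2. Immediate early genes were higher in 17 of 18 (mean 0.51, adjusted p = 3.89e-10; 0.263 with an estimated correlation; 5 rose, 14 adjusted over the list alone), by 0.705 and 0.32 within the slides. Cilia (0.24, adjusted p = 0.000336; 0.37 within slide 1 and 0.12 within slide 2), microglia (0.17), choroid plexus (0.29, 1 rose), astrocytes (0.22), glucocorticoid response (0.175, 3 rose) and oxidative stress (0.14) were shifted upward. Skeletal muscle (-0.84; -1.67 and -0.019 within the slides), cholesterol synthesis (-0.089, 1 fell), ribosomal proteins (-0.087), progenitors (-0.18, 1 fell), chromatin regulators (-0.062), cell cycle (-0.056) and DNA repair (-0.044, 1 fell) were shifted downward. The largest adjusted p of these 15 was 0.0216, and with an estimated correlation they ranged from 0.263 to 0.89.

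In the heated group cilia and hypoxia genes were higher and cell cycle genes lower than in the fresh group, as lists that did not pass with an estimated correlation (adjusted p = 0.0699, 0.0699 and 0.146). Dlx4 was at -3.81 ± 0.29 against -5.24 ± 0.33, well above background in 4 of 4 heated and 0 of 4 fresh animals, and was at least 2.52-fold higher (adjusted p = 0.00243; 0.0119 with slide as a block). The antiviral gene Ifit1 (1.37, adjusted p = 0.0497) and the costimulatory receptor Tnfrsf9 (1.27, 0.0353) rose, and Cmtm2b (-1.37, 0.0406), Neurog2 (-0.92, 0.0302) and the ventricular zone gene Dbx1 (-0.78, 0.0409) fell. Of these 6 only Dlx4 passed whichever of the 16 arrays was left out. Hspa1b (-0.48, adjusted p = 0.092), H19 (-0.24, 0.139), Hspa1a (-0.11), Mdm2 (-0.12), Igf2 (-0.07), Cdkn1a (-0.03), Eif2s3y (-2.21), Ddx3y (-1.20), Uty (-0.86) and Kdm5d (-0.58) did not pass, at adjusted p of up to 0.914. A total of 775 genes and features changed, 632 higher and 143 lower, 30 at least 2-fold, with 4740 at an unadjusted p under 0.05. Of the 775, 754 did not overlap between the groups, and 11.3% of all genes did not where chance gives 2.86%. With slide as a block 406 changed, 335 of them among the 775, and within slide 2 a total of 18 changed, all 18 higher. On the 8 arrays of the 2 groups the count was 42, and it was 0 without the arrays with pituitary, muscle or skin signal and 0 without those low in Hox genes. Without 1 array the count was 406 and 291 without fresh 1 and 2, and 443, 254, 412 and 351 without heated 1, 2, 3 and 4. Of the 775 genes, 404 also changed against the freeze-dried group, all in the same direction, and both comparisons use the same 4 heated animals. Of the 47 lists 25 were shifted, 13 upward and 12 downward. By fry 19 of the 47 passed, and 0 with an estimated correlation. Cilia genes were higher in 12 of 12 (mean 0.52, adjusted p = 3.79e-11; 0.0699 with an estimated correlation; 7 rose, 10 adjusted over the list alone; 0.47 within slide 2) and hypoxia genes in 16 of 16 (0.33, 1.76e-09; 0.0699 with an estimated correlation; 7 rose; 0.30 within slide 2). Interferon genes were higher in 19 of 19 (0.70, 4.80e-10; 0.187 with an estimated correlation; 4 rose; 0.66 within slide 2) and astrocyte genes in 14 of 14 (0.33, 3.02e-05; 0.187 with an estimated correlation). Cell cycle genes were lower in 34 of 34 (-0.26, adjusted p = 7.12e-18; 0.146 with an estimated correlation; 3 fell, 23 adjusted over the list alone; -0.195 within slide 2). Immediate early genes (0.35), microglia (0.20), glucocorticoid response (0.21), circadian clock (0.19), oxidative stress (0.15), choroid plexus (0.26), synapse (0.12), striatal neurons (0.125) and oligodendrocyte lineage (0.13) were also shifted upward. DNA repair (-0.11), heat shock and chaperones (-0.059), imprinted genes (-0.035), chromatin regulators (-0.071), ribosomal proteins (-0.033), progenitors (-0.19), thalamic neurons (-0.15), cerebellum (-0.58), Hox genes (-1.41), leukocytes (-0.27) and skeletal muscle (-1.13) were shifted downward. Single arrays carried some of these means: muscle was at 3.088 in fresh 1 (-0.338 within slide 2), leukocytes at 0.529 in fresh 2, and the Hox and cerebellum lists were low only in heated 2 and 4 among the heated animals. The oligodendrocyte list was high in heated 1 and 3 (0.2 and 0.167) but not in heated 2 and 4 (-0.065 and -0.037), and astrocytes split the same way. The largest adjusted p of these 25 was 0.0295, and with an estimated correlation they ranged from 0.0699 to 0.539.

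Irradiation and heat differed from each other in 267 genes and features, 125 higher and 142 lower in the irradiated group (85 and 42 after median centring), 43 of them at least 2-fold, with 3646 at an unadjusted p under 0.05. Wfikkn1 was at -2.87 ± 0.22 after irradiation and -4.22 ± 0.23 after heat (1.35, adjusted p = 0.006). The stress factor Atf3 was at -2.49 ± 0.12 and -3.56 ± 0.24 (1.07, 0.00506) and the hypoxia gene Adm at -1.90 ± 0.19 and -0.81 ± 0.28 (-1.09, 0.00713). These 3 passed whichever of the 16 arrays was left out. Utp14b (0.86, adjusted p = 0.019), Dlx4 (-0.94, 0.0234) and the channel Trpc7 (-0.89, 0.0153) differed as well but not without some of the arrays, Trpc7 only without irradiated 1. Hspa1b (0.50, adjusted p = 0.122), Hspa1a (0.25, 0.195), H19 (0.22, 0.227), Cdkn1a (0.09), Igf2 (-0.05), Mdm2 (0.00, 0.99), Eif2s3y (3.93), Ddx3y (2.50), Kdm5d (2.27) and Uty (2.09) did not pass. The groups did not overlap in 266 of the 267 genes, and in 13.1% of all genes where chance gives 2.86%; 181 changed with slide as a block, 124 of them among the 267, and 58 within slide 2. Without 1 array the count was 69, 55, 112 and 114 without irradiated 1, 2, 3 and 4, then 104, 47, 82 and 109 without heated 1, 2, 3 and 4, and 407 without freeze-dried 1. Of the lists 13 of 47 were shifted, 8 upward and 5 downward. By fry 5 of the 47 passed, and 0 with an estimated correlation. Cell cycle (34 of 34 higher, mean 0.20, adjusted p = 7.54e-11; 0.454 with an estimated correlation; 0.18 within slide 2), immediate early genes (0.16, 2 rose) and DNA repair (0.065) were higher after irradiation. So were cerebellum (0.59), Hox genes (2.26), thalamic neurons (0.13), meninges (0.10) and monoaminergic and cholinergic neurons (0.46). Here too the cerebellum and Hox lists were low only in heated 2 and 4 of the heated animals, and the monoaminergic list was at -1.258 and -0.244 there against 0.134 and 0.154 in heated 1 and 3. Hypoxia (16 of 16 lower, mean -0.28, adjusted p = 4.01e-10; 0.152 with an estimated correlation; 2 fell; -0.28 within slide 2) and cilia (-0.28, adjusted p = 1.44e-05; 0.243 with an estimated correlation; 2 fell; -0.35 within slide 2) were lower, as were synapse (-0.11), circadian clock (-0.13) and striatal neurons (-0.12, 2 fell). The other 10 adjusted p were at most 0.0495, and with an estimated correlation from 0.243 to 0.813.

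**Figure D3:**
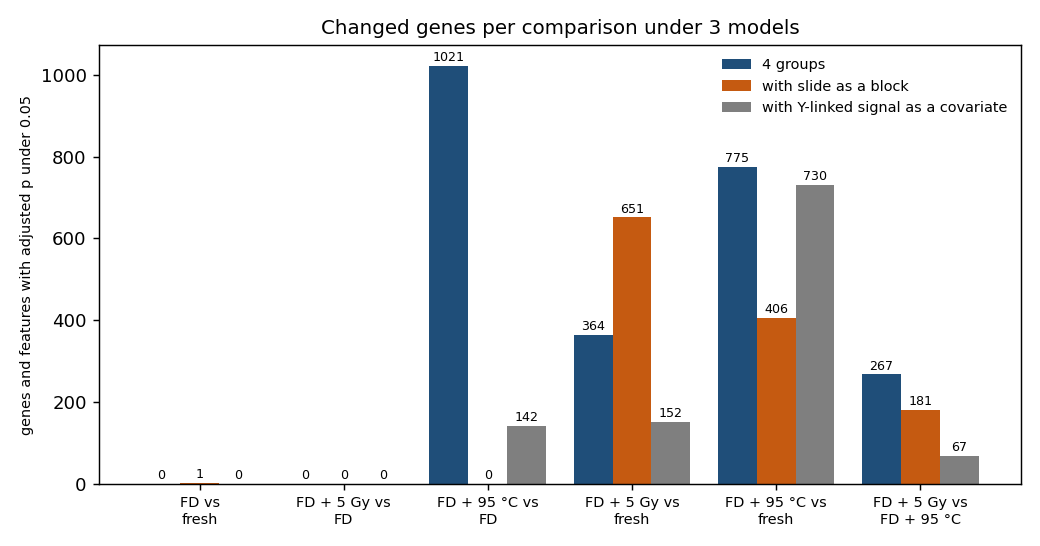
Number of genes and features with an adjusted p under 0.05 in each of the 6 comparisons, with the 4 groups alone, with slide as a block and with the Y-linked signal as a covariate. The heated against freeze-dried comparison has 1021, 0 and 142, and the irradiated against fresh comparison 364, 651 and 152.

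Across genes, the change after irradiation and the change after heat, each against the freeze-dried group, correlated with r = 0.46 over 26452 genes, which are not independent replicates. Because both changes share the freeze-dried animals, simulated data without any effect gave a mean of 0.50 (from -0.11 to 0.83 in 100 runs). With the freeze-dried animals split 2 and 2 the median r was 0.13 over 6 splits (from -0.15 to 0.26). Over all 4 groups at once 845 genes and features differed, and 320 with slide as a block. The count was 539 without freeze-dried 2, 451, 430 and 426 without irradiated 1, 2 and 3, and 333, 166, 319 and 270 without heated 1, 2, 3 and 4. The groups accounted for 29.5% of the squared distances between arrays (permutation p = 0.0118, one-sided; median of the permutations 19.6%; p = 0.0425 and 22.5% when labels were permuted only within slides, a test chosen after the data were seen) and the slides for 15.6% (permutation p = 0.00235; 6.14%). The root mean square log2 distance of an animal to its group's mean was, on average, 0.264 ± 0.053 in the fresh, 0.233 ± 0.026 in the freeze-dried, 0.185 ± 0.029 in the irradiated and 0.199 ± 0.017 in the heated group. It did not differ between groups by two-sided exact permutation tests, with p = 0.343 for freeze-dried against fresh, 0.0571 for irradiated against freeze-dried and 0.0857 for heated against freeze-dried. The adjusted values over the 6 comparisons were 0.412, 0.114 and 0.129, and 4 against 4 animals allow no p below 0.029.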

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

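The tests of slide, sex and missing hindbrain for the heated against freeze-dried genes, of slide for the cilia genes and of sex for the irradiated against fresh genes were chosen only after the result was seen.

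Single animals stood apart from the other 3 of their group in 17 of 200 checks, where chance flags about 1 in 20 groups, or 10 here. Each check was of a gene list or of 1 of 3 measures of array quality in a group, and all 17 were of gene lists. The list means, centred on all 16 arrays, were for fresh 2 -3.97 in Hox genes (others 1.17 to 1.57), 0.27 in cell cycle (others -0.01 to 0.02), 0.25 in neural progenitors (0.04 to 0.06), 0.09 in chromatin regulators (0.01 to 0.02) and -0.19 in the oligodendrocyte lineage (-0.03 to -0.02). Fresh 3 stood at -0.43 in olfactory bulb genes (others 0.01 to 0.06) and at 0.06 in choroid plexus genes (others -0.29 to -0.27), and fresh 1 at 3.09 in skeletal muscle genes (others -0.28 to 0). Freeze-dried 2 stood at 1.59 in cartilage, bone and skin genes (others -0.11 to -0.10) and at 0.04 in a list of X-linked genes written as higher in females (others 0.22 to 0.24), freeze-dried 1 at 0.05 in microglia genes (others -0.03 to -0.02) and freeze-dried 4 at -0.01 in DNA repair genes (others 0.05 to 0.06). Irradiated 1 stood at 0.03 in DNA repair genes (others all -0.02), and irradiated 2 at 0.04 in glucocorticoid response genes (others 0.07 to 0.08) and at -0.13 in olfactory bulb genes (others 0.09 to 0.11). The X-linked list ran against its name, at -0.345 to -0.201 in the 6 animals with high Xist and -0.065 to 0.259 in the other 10. In Y-linked genes irradiated 4 stood at -4.13 (others 2.24 to 2.32) and heated 4 at 1.88 (others -3.60 to -2.96).

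The pituitary hormone genes Gh and Prl lie outside the tested set, since they were above background in no complete group, and showed a signal in 3 arrays. Gh was at 2.87 in fresh 3, 2.38 in freeze-dried 1 and 2.71 in heated 1 (other arrays -7.73 to -5.60), and Prl at -3.45, -4.82 and -4.19 in the same arrays (others -8.00 to -6.66). The effects of irradiation and heat differed by a direct test in 267 genes and 13 lists, and in 0 lists with an estimated correlation (smallest adjusted p = 0.152).

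The 1021 genes that changed between heated and freeze-dried animals were weighed first, because these groups share no slide. With slide as a block their median change went from 0.404 to 0.268, which takes away 33.6% of it (28.8% to 38.0% when 1 array is left out), while its SE grew from 0.088 to 0.106 and 0 genes stayed called. A difference between the slides could thus account for part of these changes, and since the block rests on the fresh and irradiated groups alone it cannot be told apart from heat. Sex took away 3.74% (-2.49% to 8.44%) and missing hindbrain -3.24% (-9.83% to 0.509%). Both vary among the heated animals, and genes picked for a low spread within groups could hardly have given larger shares. These values therefore exclude neither. With the Y-linked signal as a covariate the median SE grew to 0.103 and 140 of the 1021 stayed called. An effect of heating the sperm remains open, and litter was not tested.

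The higher cilia genes in heated animals were weighed next. The list's mean change of 0.431 became 0.461 with slide as a block, 0.494 with the Y-linked signal and 0.434 with the choroid plexus list as a covariate. The share taken away was -6.82% (-16.6% to -0.239%) for slide, -14.5% (-19.1% to -10.4%) for sex and -0.679% (-2.88% to 1.57%) for more ventricle lining, read from the choroid plexus. The value for sex argues against sex as the source of the shift. The slide value rests on the fresh and irradiated groups alone, where the slides differed in opposite directions. The fresh animals were at -0.301 and -0.215 on slide 1 and -0.165 and -0.161 on slide 2. The irradiated animals were at 0.112 and 0.103, then -0.039 and -0.055. The slide value thus cannot exclude slide. On slide 2, however, the heated animals (0.214 to 0.385) lay above the fresh and irradiated ones, which a slide difference cannot explain. The choroid plexus list hardly differed between the groups (0.064 heated, 0.037 freeze-dried), so as a covariate it could take away little. Nor did it follow the cilia list among the heated animals, being higher in heated 1 and 3 and lower in heated 2 and 4. Whether more ventricle lining was sampled therefore stays open. A change in the ependyma of these pups may be the source, as a hypothesis found and tested on the same data, but a difference in litter or in the age at sampling within the day was not tested, and the list did not pass with an estimated correlation (adjusted p = 0.107).

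The 364 genes that changed between irradiated and fresh animals were weighed last, because neither freeze-drying alone nor irradiation alone called any gene. With the immediate early list as a covariate, a reading of handling before freezing, their median change went from 0.467 to 0.311, which takes away 33.4% (22.9% to 44.4%), and the median SE rose from 0.091 to 0.153, so that 0 genes stayed called; handling may therefore contribute, and it cannot be told apart from the treatment because the list itself differs between the groups. Sex took away 0.718% (-0.729% to 7.59%), but both groups hold animals high and low in Y-linked genes. Genes picked for a low spread could thus hardly have shown a large share, and sex stays open. With the Y-linked signal as a covariate 145 of the 364 stayed called. Leaving out any 1 fresh array took away at most 1.99% (-8.31% to 1.99%), but genes picked for a low spread could hardly have given another value, and the count fell to 139, 111 and 185 without fresh 1, 2 and 3, so a single fresh array stays open. Each step carried part of the change in these genes: a median of 0.24 between freeze-dried and fresh animals (98.6% with the same sign) and 0.239 between irradiated and freeze-dried animals (98.9%), which is partly arithmetic, since the genes were picked for the sum of these steps. A combined effect of drying and irradiation remains open.

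Other splits of the 8 arrays of each comparison into 4 and 4 were fitted in the same way, 35 in all with the real one. For heated against freeze-dried animals 1 split called 1021 genes, the real one, and the highest other called 0. Only the real split stood out for heated against fresh (775, highest other 7) and irradiated against heated (267, highest other 0). Such counts are thus rare among splits of these arrays, but 1 of 35 is the smallest share this test can give. The splits also did not hold slide fixed. For heated against freeze-dried the real split is the split by slide. In the other 2 comparisons the heated group had 4 arrays on slide 2 and the other group 2. Slide, sex and litter are therefore not excluded. Over all 4 groups 1 of 100 splits called as many as the real 845 (highest other 30), again without holding slide fixed. For irradiated against fresh 2 of 35 splits called at least 364 genes, so chance cannot be excluded by this count; the other split called 1246 genes and follows the slides exactly, while the real comparison gave 414 and 1 genes within the slides and 651 with slide as a block. For freeze-dried against fresh and irradiated against freeze-dried the real count was 0, which all 35 splits reach, so these counts exclude nothing. One other split of the former, fresh 1, fresh 3, freeze-dried 3 and freeze-dried 4 against the rest, called 1330 genes, with 1 array of slide 2 on each side. One split of the latter, freeze-dried 1, 2 and 3 with irradiated 1 against the rest, called 109. Splits that call many genes point to a structure of the samples other than treatment. For lists, 16 of 35 splits shifted at least the 7 of freeze-dried against fresh (highest other 22), 2 at least the 13 of irradiated against freeze-dried (highest other 17) and 3 at least the 19 of heated against freeze-dried (highest other 23), so chance cannot be excluded for these counts.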

How the results depend on the processing

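The fits with the Hox signal as a covariate, with slide block and Y-linked covariate together, and without the 5 arrays with pituitary, muscle or skin signal or the 4 arrays low in Hox genes, and the permutation within slides, were chosen only after the result was seen. Where a count moved, the cause was not tested, except that fits within a slide, on 8 arrays or without some arrays have fewer samples and that the deposited value table differs from the scanner values mainly between slides.

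Heated against freeze-dried (1021 genes) was 117 with median centring, 609 without the filter, 0 with slide or scan batch as a block, 3341 with array weights, 142 with the Y-linked covariate and 0 with the value table. It was 2026 on 8 arrays, 2829 with the Hox covariate, 1 with slide block and Y-linked covariate, 247 without the arrays with other tissue and 12 without those low in Hox genes. The genes called were not always the same. Among the 1021 were 922 of the 1120 called with quantile normalization but 683 of the 1273 with normexp. Without the filter 384 of the 609 were among them, and without the arrays with other tissue 107 of the 247. Irradiated against fresh (364) was 208 with normexp, 140 with median centring, 71 without the filter, 651 with slide or scan batch as a block, 983 with array weights, 152 with the Y-linked covariate and 939 with the value table. It was 69 on 8 arrays, 1 within slide 2, 222 without the arrays with other tissue and 0 without those low in Hox genes. Heated against fresh (775) was 84 with median centring, 267 without the filter, 406 with slide or scan batch as a block, 1669 with array weights and 312 with the value table. It was 42 on 8 arrays, 18 within slide 2, 1384 with the Hox covariate, 391 with slide block and Y-linked covariate, and 0 without either set of arrays. Irradiated against heated (267) was 109 with normexp, 127 with median centring, 95 without the filter, 177 with replicate number as a block, 1540 with array weights, 67 with the Y-linked covariate and 112 with the value table. It was 725 on 8 arrays, 58 within slide 2, 116 with slide block and Y-linked covariate and 19 without the arrays low in Hox genes. The count over any group (845) was 158 with median centring, 206 without the filter, 320 with slide or scan batch as a block, 1659 with array weights, 336 with the Y-linked covariate and 226 with the value table. It was 1497 with the Hox covariate, 202 with slide block and Y-linked covariate, 408 without the arrays with other tissue and 0 without those low in Hox genes. Freeze-dried against fresh (0 by limma, 2628 at an unadjusted p under 0.05) was 1 with each probe on its own, 1 with slide or scan batch as a block and 20 without the arrays with other tissue. Irradiated against freeze-dried (0, 1912) was 1 with array weights. Quantile normalization, the mean of a gene's probes and the filter on all 16 arrays kept all 7 counts within 1.5 times. Probes of a called gene did not always agree, however. Among called genes with several probes, a probe had the opposite sign in 52 of 286 for heated against freeze-dried and 17 of 68 for irradiated against fresh. It was 27 of 215 for heated against fresh and 13 of 48 for irradiated against heated.

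Leaving out 1 array gave 0 to 4 genes for freeze-dried against fresh, 0 to 3 for irradiated against freeze-dried and 181 to 1554 for heated against freeze-dried. It gave 54 to 539 for irradiated against fresh, 254 to 1126 for heated against fresh, 47 to 407 for irradiated against heated and 166 to 880 over any group. The lists shifted were then 4 to 10 for freeze-dried against fresh, 7 to 16 for irradiated against freeze-dried and 18 to 23 for heated against freeze-dried, and the variance between groups 28.9% to 33.6%. With labels permuted only within slides its permutation p was 0.0425 in place of 0.0118.

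With an estimated correlation the lists shifted were 0, 0 and 0 in these 3 comparisons, and with fry 0, 0 and 11. The list count was 14 for freeze-dried against fresh without the filter and 8 for irradiated against freeze-dried without the arrays with other tissue. Under normexp, quantile normalization, slide or replicate number as a block and the covariates it stayed within 1.5 times, and median centring, array weights, the value table, the filter on all 16 arrays, the mean of a gene's probes, each probe on its own and fits on 8 arrays or within a slide were not tried on lists. Spread was smaller among irradiated than among freeze-dried animals with normexp (-0.0426, exact p = 0.0286) and without the filter (-0.0479, exact p = 0.0286). With normexp it was also smaller among heated than among freeze-dried animals (-0.05, exact p = 0.0286). These are the smallest p that 4 against 4 animals allow, and they were not adjusted over comparisons or settings, so they do not establish a difference. The correlation of the irradiation and heat effects went from 0.46 to 0.13 with the freeze-dried arrays split 2 and 2. The split removes the shared animals but also leaves only 2 freeze-dried arrays behind each change, so the drop cannot be put down to sharing alone.

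Of the 266 named gene values, most had no call to lose. Those that passed were 59 for heated against freeze-dried and 6 each for irradiated against fresh, heated against fresh and irradiated against heated. Of these calls, 64 were lost with slide as a block, 54 with the Y-linked covariate and 7 with quantile normalization. Direction and side of the threshold were kept by 196, 200 and 253 of the 266 values. Values that reversed were Trappc9 in heated against freeze-dried (0.10 with the mean of its probes), skeletal muscle in freeze-dried against fresh (0.058 without the arrays with other tissue, from -0.935 without fresh 4 to 0.189 without fresh 1 when 1 array was left out) and the Hox list in heated against freeze-dried (0.312 without the arrays low in Hox genes), the last 2 because the arrays that carried the difference were removed. Signal over background limits what could be seen: 59.9% to 66.1% of spots were well above background, and genes without a group in which all 4 arrays were above it, such as Xist, were not tested. The mean signal planned for normexp was not used here, and the median signal took its place; all other alternatives chosen beforehand were run.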

Other observations

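The features without a gene symbol described here, the marker genes of single arrays and the grouping of their values were chosen only after the result was seen.

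Most of the larger changes between irradiated and fresh animals lay in features without a gene symbol. Of 52 genes and features that changed at least 2-fold, 48 had no symbol (92.3%, against 39.6% of all tested and 46.7% of the 364 that changed), and 44 of the 52 were higher. The 40 features without a symbol that rose at least 2-fold had centred means of 0.75, 0.86, 0.96 and 0.96 in irradiated 1 to 4 and of -0.77, -0.91, -0.59 and -0.27 in fresh 1 to 4, as their selection requires. The levels of the other groups did not enter that difference, though their arrays set part of the variance in the shared fit by which the features were called. Freeze-dried 1 was at -0.48 and freeze-dried 2, 3 and 4 at 0.10, 0.43 and 0.58, while the heated animals lay at -0.41, -0.37, -0.49 and -0.34. Freeze-dried 1 thus lay near the heated and fresh animals, and the other freeze-dried animals lay between these and the irradiated ones. The immediate early list was at -0.40, -0.62, -0.14 and -0.04 in fresh 1 to 4 and at -0.05, 0.05, 0.05 and 0.11 in freeze-dried 1 to 4. It was at 0.04, 0.04, 0.11 and 0.02 in the heated animals, so these features and the immediate early genes did not move together there. Which transcripts these probes measure was not analysed here.

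Markers of neighbouring tissue came and went as sets. The pituitary prohormone gene Pomc was at 2.89 in fresh 3, 2.85 in freeze-dried 1 and 3.10 in heated 1, the arrays with Gh, and at -1.11 to -0.62 in the other 13. Hoxc4 followed Hoxb5, at -7.68 in fresh 2, -7.21 in heated 2 and -6.96 in heated 4, and at -2.25 in freeze-dried 2. The choroid plexus gene Ttr varied little, from 5.23 to 5.87 over the 16 arrays, as did the haemoglobin gene Hba-a1 (7.54 to 8.05), while the erythroid enzyme gene Alas2 ranged from 0.63 to 2.96.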
